A study of Arabidopsis thaliana with 6 samples.

How the data were processed

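Rosettes of Arabidopsis thaliana were compared between the wild type Col-0 and the sid2.2 mutant, which carries a mutation in ICS1, the isochorismate synthase of salicylic acid (SA) synthesis. Per the labels, plants were kept at 0.016 mM sulfate until day 60, with 8 h of light at 160 µmol per m2 and s and 16 h of dark. Each of 3 cultures, run months apart, gave 1 pool of more than 6 plants per genotype, so there were 3 arrays per group and 6 in all. Targets were made from 200 ng of total RNA per pool and hybridised to a 3'-biased oligonucleotide array with 22810 probe sets, 64 of them controls.

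The deposited table holds linear signal intensity per probe set, made with MAS5 per the submitters' processing notes. Its version, and the image analysis before it, are not given in the sources used here. The values were checked against that description: after the highest and lowest 2% were left out, each array had a mean between 499.76 and 499.79, as scaling to a common target would give. MAS5 subtracts background and combines the probes of a set within each array, so values near background are noisy on a log scale, and scaling removes any change in total signal per cell. For arrays no counting depth exists, and the 3 arrays per genotype limit the precision; the median residual SD was 0.33 (log2).

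Probe sets were named only through the platform annotation that came with the table, with symbols updated by gene identifier from a RefSeq gene table (assembly TAIR10.1), which also gave the order of genes along a chromosome. Of the 22810 probe sets, 13513 had 1 gene name, 503 had several and 8794 had none. No probe set was named ICS1, PR1, BGL2, PR5, SDI1 or LSU1, so these genes were not analysed here, and no probe set of ICS1 could check the genotype labels.

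Intensities were log2 transformed without further scaling. The 40% of probe sets with the lowest mean over the 6 arrays and the controls were left out, which kept 13647 probe sets, 7387 of them with 1 gene name, 273 with several and 5987 with none. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; two-sided). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. TRZ1, next to ICS1, lies under the low-signal limit and was tested in a second fit that kept it whatever its level. A fold for a probe set at background in one genotype was given as at least N-fold, with the dim arrays set to the 95th percentile of the bacterial control probe sets.

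Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 5 tested members, and checked with an estimated correlation and with the rotation test fry. The 23 planned lists held 375 entries, of which 55 had a named probe set and 49 were tested; 0 entries were dropped for a symbol that belonged to another locus. Only autophagy reached 5 tested members. A further 17 lists, by symbol family or by loci taken from general knowledge, were chosen after the probe annotation had been seen and with no genotype difference yet computed. Adjustment ran over the 18 lists. A gene with several probe sets was represented by the one with the highest mean.

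The groups, tests, planned lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named ICS1 and its neighbours on both sides, the strongest calls with 1 gene name and the same direction in all 3 cultures, up to 4 members of each list with the smallest p, and BGLU28 among 6 fixed names. Because fewer than 10 probe sets passed with or without the culture block, its fallback applied: the 10 higher and the 10 lower genes with the smallest p, most of which did not pass. The list part was applied also to the added lists that passed the set test, after their results had been seen.

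The labels give each culture number to 1 array of each genotype, and a culture is a shared batch, so the numbers pair the arrays and culture was an alternative block. The data were checked for this pairing: deviations from the genotype mean correlated across probe sets at -0.03, -0.53 and -0.55 for the same-numbered arrays of cultures 1, 2 and 3. Such deviations sum to 0 within a genotype, so 1 strong deviation shared by arrays of different cultures lowers these values. They are therefore not separate checks of each pair. The limma F test of culture beside genotype called 0 probe sets, with 29 at an unadjusted p under 0.05 (smallest adjusted p = 0.9999).

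The fit was tested on simulated data for sid2.2 against Col-0, with 200 probe sets changed in each of 20 data sets. Values for the 13647 probe sets were drawn from their means and limma's moderated SDs, independently for each probe set. Of the 50 changed 2-fold, 23.1% were called, against 92.3% at 4-fold, 99.5% at 8-fold and 100% at 16-fold. On average 10.8 unchanged probe sets per data set were called, 6.42% of the calls outside the shifted list below and so above the nominal 5%. A limit of 10 set beforehand for this number was exceeded and then dropped; the fit was not changed. A list of 20 genes shifted by 0.5 (log2) had an unadjusted camera p under 0.05 in 100% of the data sets, and an unshifted list in 0%. The real lists needed an adjusted p under 0.05 over 18 lists, a stricter limit. The simulation holds no correlation between genes and no shared deviation between arrays, so these list rates do not carry over to lists whose members move together.

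Alternatives were the culture block, culture as a random block, quantile normalization, median centring, no and a stricter low-signal filter (60%), a pseudocount of 22.3 (the 20th percentile of all intensities), eBayes without a trend or robust, each array left out, and each culture left out. Leaving out Col-0 replicate 3 and sid2.2 replicate 2 together was added after the data had been seen. No scaling moved the median log2 difference of all tested probe sets past 0.1; it lay between -0.085 and -0.0041.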

Results

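Expression was measured in rosettes of Col-0 and sid2.2 plants under low sulfate, with 1 array per genotype from each of 3 cultures. The comparison asks how the rosette transcriptome differs when the ICS1 route to SA, a hormone of pathogen defence, is mutated. Median intensities per array lay between 130.73 and 162.26. The arrays are named by genotype and culture number, so Col-0 replicate 3 and sid2.2 replicate 3 come from culture 3.

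Of the genes next to ICS1, the mutated gene itself not analysed here, TRZ1 was at background in the mutant. TRZ1, which encodes a tRNA 3'-processing enzyme, had signals of 200.94, 146.22 and 149.66 in Col-0 (mean 166 ± 30.6, SD, n = 3). In sid2.2 the signals were 10.6, 13.8 and 8.09 (mean 10.8 ± 2.84, SD, n = 3). TRZ1 fell by 3.96 on the log2 scale (SE 0.36; limma adjusted p = 0.0138), in the fit of 13648 probe sets that kept it, and was at least 4.65-fold lower against the background level. That fit called 5 probe sets, 3 higher and 2 lower. Besides TRZ1 these were AT1G26390, AT4G12500, PDF1.4 (adjusted p = 0.0464 there, 0.393 with the block) and 262177_at. The call was lost with culture as a block (adjusted p = 0.276) and without the low-signal filter (adjusted p = 0.0597); over all 17 alternatives the adjusted p ran from 0.00168 to 0.999. It was also lost without Col-0 replicate 1 (0.324) or 2 (0.0673), sid2.2 replicate 1 (0.122) or 3 (0.0733), culture 1 (0.999) or culture 2 (0.0661). QKY, on the other side of ICS1, differed by 0.28 (SE 0.36; adjusted p = 0.874). The genes beyond, IQD31 and AT1G74730, had log2 differences of 0.0097 and -0.32, with overlapping signals.

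**Figure D1:**
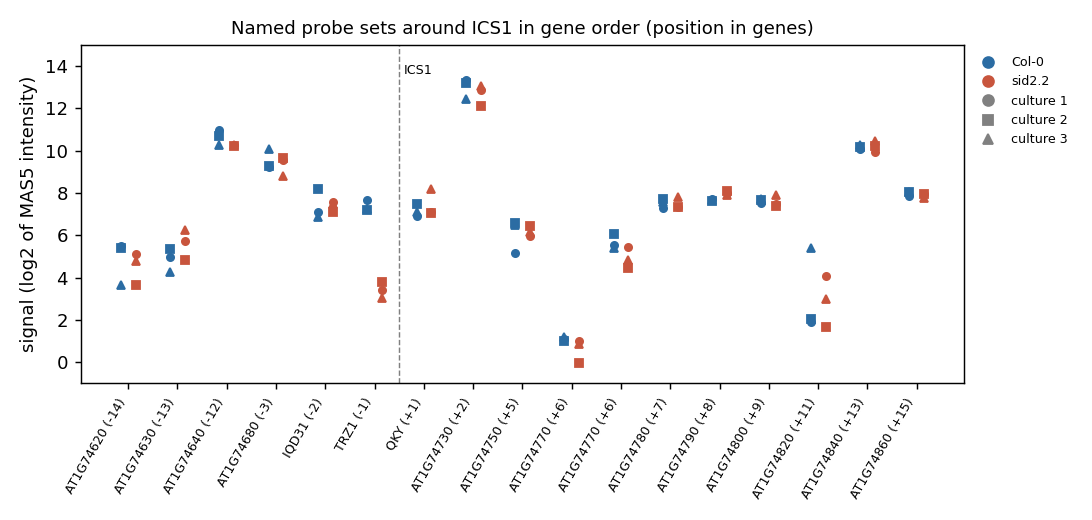
Signal (log2 of MAS5 intensity) of the 17 named probe sets among the 15 genes on each side of ICS1, in gene order, with 1 point per array coloured by genotype and shaped by culture. TRZ1 is the probe set whose sid2.2 arrays (8.09 to 13.8) lie furthest below the Col-0 arrays (146.22 to 200.94).

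In the fit over all probe sets past the low-signal filter, which leaves out TRZ1, 2 named genes passed and both rose in sid2.2. AT1G26390, of the berberine bridge enzyme-like oxidase family, rose 18.7-fold (log2 4.23, SE 0.45, adjusted p = 0.0495), from 86.2, 66.1 and 216 in Col-0 to 1758, 3005 and 1526. AT4G12500, of the lipid transfer protein family, rose 8.69-fold (log2 3.12, SE 0.35, adjusted p = 0.0495). The probe set that fell, 262177_at, has no gene name in the annotation used, and whether it measures ICS1 or another unnamed gene was not tested. It was at least 9.26-fold lower against the background level (log2 -3.32, SE 0.29, adjusted p = 0.0209), with signals of 397, 270 and 360 in Col-0 against 31.3, 29.7 and 41.6, where the bacterial controls reached 39.4, 27.9 and 39.9 (95th percentile). Within cultures 1, 2 and 3 the differences were 4.35, 5.51 and 2.82 for AT1G26390, 2.45, 4.29 and 2.61 for AT4G12500, and -3.67, -3.18 and -3.11 for 262177_at.

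In all, 3 of 13647 probe sets were called by limma, 2 higher and 1 lower, and 1010 had an unadjusted p under 0.05 (634 higher, 376 lower), where chance gives 682. The 9 other splits of the 6 arrays into 3 and 3, which mix the genotypes, gave 53 to 3262, so this excess does not stand out. With culture as a replicate block 0 were called (550 at an unadjusted p under 0.05). The blocked adjusted p was 0.414 for AT1G26390, 0.475 for AT4G12500 and 0.3996 for 262177_at. Over their 17, 17 and 16 alternatives the adjusted p ran from 0.000178 to 0.999, from 0.00238 to 0.999 and from 0.00242 to 0.999. The calls were 0 higher and 1 lower with quantile normalization, and 1 higher and 1 lower with median centring. The arrays of the genotypes did not overlap for 1636 probe sets (11.99%, where chance gives 10%), 874 higher and 762 lower. All 3 cultures had the same sign for 2934 (21.5%, where chance gives 25%).

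The count depended on which arrays were kept. Without Col-0 replicate 3 limma called 302 probe sets (238 higher, 64 lower), without culture 3 it called 728 (459 higher, 269 lower), and without any other single array or culture 0. Without Col-0 replicate 3 and sid2.2 replicate 2, a choice made after seeing the data, it called 235 (179 higher, 56 lower). The calls of AT1G26390 and AT4G12500 were lost without Col-0 replicate 1 (adjusted p = 0.396) or 2 (0.104), without sid2.2 replicate 1 (0.230), 2 (0.112) or 3 (0.203), without culture 1 (0.999) and without culture 2 (0.139), with the same value for both. For 262177_at these were 0.396, 0.0605, 0.230, 0.0932, 0.0692, 0.999 and 0.0882. The log2 differences themselves stayed at 3.59 to 4.93, 2.53 to 3.45 and -3.48 to -3.15 with any array or culture left out.

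The other 8 of the 10 higher genes with the smallest p did not pass in this fit. All 8 passed in some alternatives that left out Col-0 replicate 3, alone or with another array. OSM34 had the lowest of these values, with a limma adjusted p of 0.00104 to 0.999 over 17 alternatives. PDF1.4, a plant defensin, differed by 2.76 (SE 0.32, adjusted p = 0.0583, and 0.0464 in the fit that kept TRZ1), with 42.4, 51.7 and 32.0 in Col-0 against 201, 349 and 311. AT1G68620 differed by 2.72 and AT3G61390 by 2.34 (both adjusted p = 0.0988). AT4G12490, of the family of AT4G12500, differed by 2.97 (adjusted p = 0.0988). OSM34, an osmotin-like thaumatin protein, differed by 3.51 (SE 0.50, adjusted p = 0.105). AT2G38870, a proteinase inhibitor, differed by 1.86 (adjusted p = 0.171), AT1G03660 by 1.54 and AT4G16260, a glucanase-family protein, by 2.60 (both adjusted p = 0.269).

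None of the 10 lower genes with the smallest p passed in this fit. With Col-0 replicate 3 left out, alone or with another array, all but AT5G44680 and AT1G28100 passed in at least 1 alternative. AT4G32340 had the lowest of these values, with a limma adjusted p of 0.00627 to 0.999 over 17 alternatives. The log2 differences were -1.20 for AT5G44530, a subtilase, -1.39 for AT3G62550 and -1.62 for AT4G32340 (each adjusted p = 0.289). They were -0.91 for AT5G44680 (adjusted p = 0.359), -1.14 for AT3G23080 (0.387), -1.31 for AT5G11070 (0.394) and -0.88 for AT1G28100 (0.404). For AT1G75460, AT5G63100 and AT1G51080 they were -0.91 (0.404), -1.43 (0.443) and -1.27 (0.453).

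**Figure D2:**
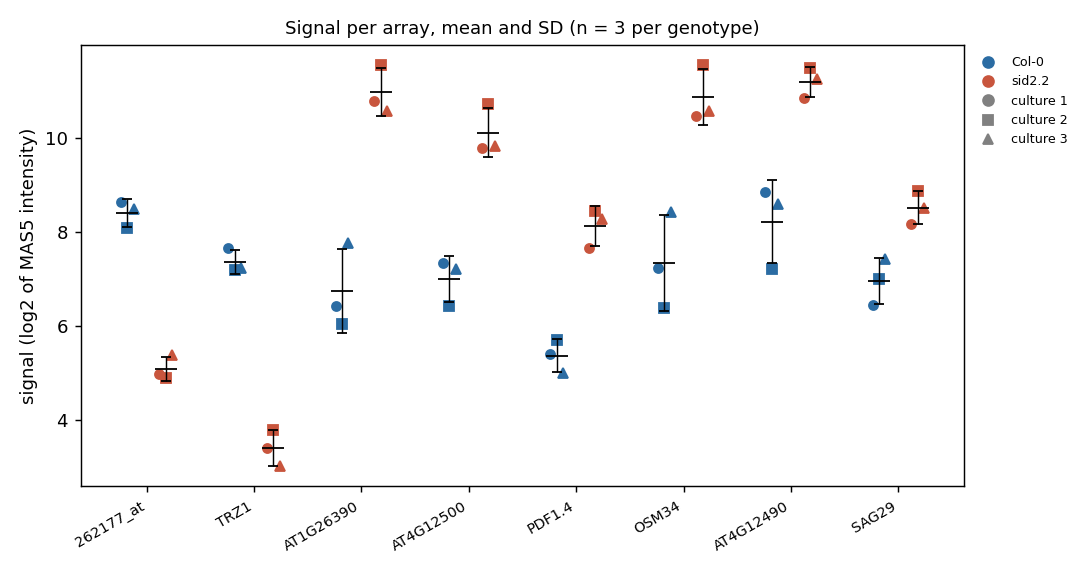
Signal per array (log2 of MAS5 intensity) of 8 probe sets, with Col-0 in blue, sid2.2 in red, culture by shape, and the mean and SD of n = 3 as bars. AT1G26390 in Col-0 replicate 3 (216) lies nearest the sid2.2 arrays (1526 to 3005), while 262177_at there (360) lies among the Col-0 arrays (270 to 397).

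SA- and pathogen-responsive genes, an added list taken by locus, passed the set test as higher in sid2.2 at the preset correlation. Of 19 tested members 17 were above 0, with a median of 0.29 and a mean of 0.87 (camera adjusted p = 2.33e-05). The adjusted p was 0.595 with an estimated correlation, and 3.50e-09 to 0.675 over its 20 alternatives. The median was 0.33, 1.05 and 0.37 within cultures 1, 2 and 3. No member was called over all probe sets, while 6 were higher adjusted over the list alone. AT1G26380, AT5G44380 and AT1G26420, of the oxidase family of AT1G26390, differed by 2.93 (SE 0.67), 2.52 (SE 0.59) and 1.97 (SE 0.48), and AT3G18250 by 2.23 (SE 0.48). The smallest adjusted p of these was 0.348. The set call was lost without culture 2 (adjusted p = 0.0548) and without Col-0 replicate 3 and sid2.2 replicate 2 (adjusted p = 0.0531). Without these 2 arrays the median was 0.0082, and sid2.2 replicate 2 lay above the other sid2.2 arrays by a median of 0.93. The members named above, picked for the smallest p of the list, were nevertheless called by limma without these 2 arrays. AT1G26380 differed by 3.43 (adjusted p = 0.00156), AT3G18250 by 2.57 (0.00975), AT5G44380 by 2.92 (0.0120) and AT1G26420 by 1.88 (0.0345). The signal ratio of 3' over 5' actin probe sets, a measure of RNA integrity and target length, was also higher on all sid2.2 arrays (5.34, 6.51 and 8.34 against 4.91, 4.85 and 4.81).

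The planned SA lists held few named probe sets and 0 calls, also when adjusted over the list alone. Among 3 tested members of SA synthesis and signalling, WRKY53 differed by 0.39 (adjusted p = 0.750), AT5G52810 by -0.10 (0.950) and SAG101 by 0.042 (0.985). The sign of SAG101 turned with both scalings. GRX480, the tested SA-responsive defence gene, differed by 0.61 (adjusted p = 0.801), and AIM1, of the phenylalanine route, by 0.41 (adjusted p = 0.745). The jasmonate and ethylene branch had PDF1.2b at 2.01 (SE 1.02, adjusted p = 0.742) and PDF1.2 at 1.80 (SE 0.98, adjusted p = 0.745). Both defensins were lowest in Col-0 replicate 3, with signals of 26.3 and 17.2. JMT, which methylates jasmonate, differed by 0.40 (adjusted p = 0.783).

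At the preset correlation, autophagy genes passed the set test as higher in sid2.2, the one planned list large enough to test. All 13 tested members lay above 0, with a median of 0.31 (camera adjusted p = 0.0204 over 18 lists). The correlation estimated between its members was 0.79, far above the preset 0.01. The adjusted p was 0.640 with an estimated correlation, and 0.000282 to 0.675 over its 20 alternatives. Over all probe sets 0 members were called, and 0 adjusted over the list alone. ATG8H, ATG8E, ATG8D and ATG8F, which encode the ubiquitin-like protein of autophagosome membranes, differed by 0.79, 0.75, 0.51 and 0.44 (smallest adjusted p = 0.788). The group median was 0.25, 1.07 and -0.37 within cultures 1, 2 and 3, and the direction turned without culture 2 (adjusted p = 0.419). The call was lost without Col-0 replicate 2 (0.591) or sid2.2 replicate 2 (0.461), and kept without Col-0 replicate 3 and sid2.2 replicate 2 together, with a median of 0.38. The list level on Col-0 replicate 3 (0.41) lay above sid2.2 replicates 1 (-0.0090) and 3 (-0.090), and the actin ratio moved with this list and the next between genotypes (mean 4.86 against 6.73). Calmodulin-like calcium sensors, an added list, also passed as higher at the preset correlation: 5 of 6 lay above 0, with a median of 0.52 (adjusted p = 0.0204). For these the adjusted p was 0.595 with an estimated correlation, and 0.00376 to 0.675 over 19 alternatives. CML38 differed by 1.55 (SE 0.37), CML37 by 0.90, CML41 by 0.73 and CML23 by 0.31. Of these CML38 passed adjusted over the list alone. The median was 0.24, 1.13 and 0.13 within the cultures. The set call was lost without Col-0 replicate 2 (adjusted p = 0.1004) or 3 (0.0591), sid2.2 replicate 2 (0.149) or culture 2 (0.566), and without Col-0 replicate 3 and sid2.2 replicate 2 together (0.177).

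Chloroplast-encoded transcripts passed the set test as lower in sid2.2 in 3 added lists, at the preset correlation. For photosystem, cytochrome b6f, ATP synthase and Rubisco genes 26 of 32 lay below 0, with a median of -0.32 (adjusted p = 2.33e-05). The adjusted p was 0.595 with an estimated correlation, and 3.56e-09 to 0.675 over 20 alternatives. All 8 tested NADH dehydrogenase-like genes lay below 0, with a median of -0.40 (adjusted p = 0.00717). Here the adjusted p was 0.595 with an estimated correlation, and 0.000292 to 0.675 over 20 alternatives. Of 17 ribosomal protein and RNA polymerase genes 14 lay below 0, with a median of -0.29 (adjusted p = 0.00582). Its adjusted p was 0.595 with an estimated correlation, and 0.000282 to 0.953 over 20 alternatives. Across the 3 lists 0 members were called, and 0 adjusted over the list alone.

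Within cultures 1, 2 and 3 the medians were -0.46, -0.86 and 0.29 for the photosynthesis genes, -0.56, -0.94 and -0.18 for the NADH dehydrogenase-like genes, and -0.077, -0.99 and 0.067 for the ribosomal and polymerase genes. Examples with their log2 differences were atpI at -1.35, psbH at -0.69, psbE at -0.62, atpF at -0.77, ndhA at -0.95, ndhG at -0.64, ndhE at -1.06 and ndhD at -0.60. In the last list rpoC1 was at -0.84, rpl33 at -0.65, rps16 at -0.66 and rpl32 at -0.35. Without culture 2 the 3 lists had adjusted p values of 0.221, 0.175 and 0.953, the last with its direction turned. The NADH dehydrogenase-like list was lost without culture 1 (0.0595), and the ribosomal and polymerase list without Col-0 replicate 2 (0.339) or sid2.2 replicate 2 (0.116). All 3 calls were kept without Col-0 replicate 3 and sid2.2 replicate 2 together, with medians of -0.36, -0.53 and -0.32. The actin ratio moved with these lists between genotypes too. It was 4.91, 4.85 and 4.81 in Col-0 and 5.34, 6.51 and 8.34 in sid2.2 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The GAPDH ratio was 2.63 ± 0.26 against 3.35 ± 0.48 (SD, n = 3; exact permutation p = 0.1).

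**Figure D3:**
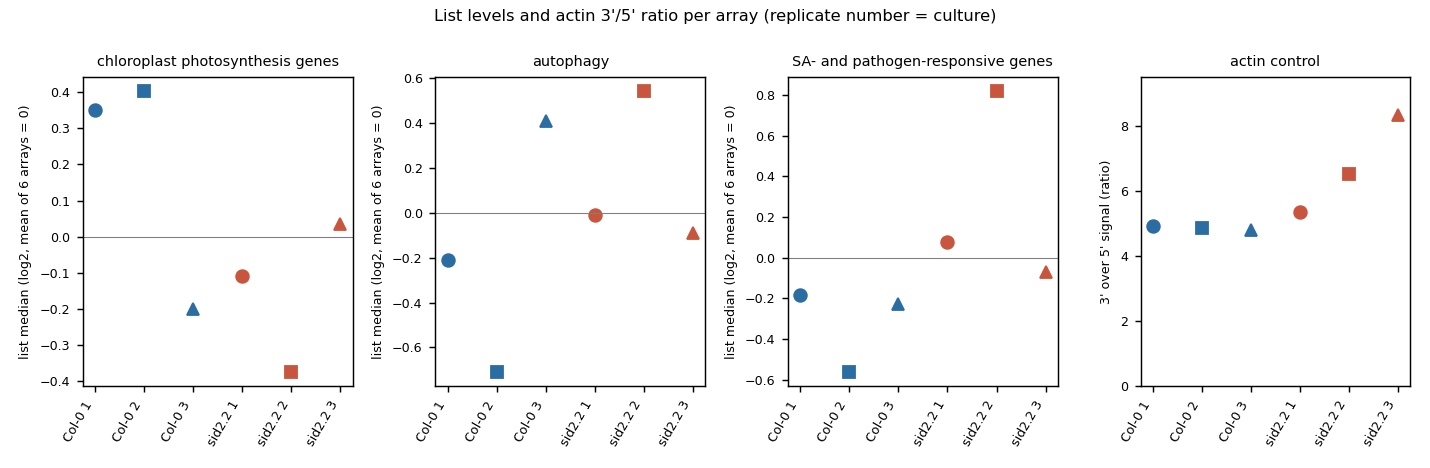
Median level of 3 gene lists per array (log2, mean of the 6 arrays set to 0) and the 3' over 5' signal ratio of actin, with replicate number as culture. Col-0 replicate 3 lies with the sid2.2 arrays for chloroplast photosynthesis genes (-0.20) and autophagy (0.41), while its actin ratio (4.81) lies with Col-0.

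Nuclear photosynthesis genes were too few for a set test, with 4 tested, and their median was 0.065, -0.98 and 0.77 within the cultures. None passed. LHCB4.1 differed by 0.15 (adjusted p = 0.887), RCA by 0.20 (0.885), PRK by -0.11 (0.952) and SBPASE by -0.37 (0.826). The senescence list had 0 calls over all probe sets and 2 of 2 higher adjusted over the list alone. SAG29, a SWEET sugar transporter, differed by 1.56 (SE 0.32, adjusted p = 0.348) and the transcription factor WRKY6 by 1.07 (SE 0.37, adjusted p = 0.581), both without overlap between genotypes. The glutathione transferase and antioxidant list likewise had 0 calls and 2 of 2 higher adjusted over the list alone. GSTU25 differed by 1.61 (SE 0.49, adjusted p = 0.523) and UGT73B5 by 1.18 (SE 0.46, adjusted p = 0.633).

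Sulfate-related genes, of interest because all plants were sulfate-limited, did not pass in any direction, nor adjusted over the list alone. BGLU28, a thioglucosidase used as a marker of sulfate deficiency, differed by 1.11 (SE 0.73, adjusted p = 0.775), and by 0.78, 3.50 and -0.93 within the cultures. AT1G04770 differed by -0.14 (adjusted p = 0.919). In sulfate assimilation, SIR, a sulfite reductase, differed by 0.26 (0.840), and the ATP sulfurylases APS3 and APS4 by -0.18 (0.913) and -0.20 (0.950). For glucosinolate synthesis BCAT4 differed by -0.61 (SE 1.08, 0.913), AT2G31790 by -0.11 (0.959) and UGT74B1 by 0.16 (0.913).

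The remaining planned lists had 0 calls, over all probe sets and adjusted over the list alone. Anthocyanin genes UF3GT, AT4G14090 and DFR differed by 1.005 (adjusted p = 0.793), 0.88 (0.812) and 0.62 (0.841). Their highest signals, 2366, 2737 and 4674, were all in sid2.2 replicate 3. Cold and drought genes COR15B, COR15A, LTI30 and COR47 differed by -1.15 (0.799), -0.94 (0.862), 0.43 (0.791) and 0.28 (0.874). The clock gene GI, a check of harvest time, differed by 1.07 (0.788), with 0.65, -1.17 and 3.73 within the cultures. The folding genes CRT1b and ATERDJ3B differed by 0.29 (0.848) and 0.033 (0.976, turned by median centring), and PYE, of the iron list, by -0.13 (0.927). The root marker PYK10 differed by 0.14 (0.971). The lists for nitrogen, heat shock, phosphate and flowers had 0 tested members.

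Of the added lists the other 12 did not pass. Expansins and xyloglucan endotransglucosylases had a median of -0.24, with all 10 below 0 (camera adjusted p = 0.0629). Plant U-box ligases had 0.46 (0.0629), UDP-glycosyltransferases 0.18 (0.0527) and beta-glucosidases 0.47 (0.272). Tetraspanins had -0.23 (0.243), serine carboxypeptidase-like proteins -0.12 (0.458) and wall acetylation proteins -0.22 (0.458). Cytochrome P450 71B genes had a median of -0.064 and a mean of 0.20 (0.411), and tau glutathione transferases -0.040 and 0.28 (0.585). SWEET transporters had -0.026 (0.585) and cytosolic ribosomal proteins -0.0064 over 73 genes, with a mean of 0.0064 (0.782). The SWEET list, with 0.28 as its highest member, leaves out SAG29 (1.56). AGAMOUS-like factors, mostly of reproductive tissue, had a median of 0.023 and a mean of -0.13 (0.782). With culture as a replicate block 8 lists passed, UDP-glycosyltransferases (adjusted p = 0.0464) and expansins (adjusted p = 0.04999) being added. The adjusted p of both was 0.675 with an estimated correlation and the block, and 0.595 and 0.627 with an estimated correlation alone. Median centring added UDP-glycosyltransferases and U-box ligases (both adjusted p = 0.0420, and 0.595 with an estimated correlation). Over their 20 and 19 alternatives these ran from 0.00930 to 0.675 and from 0.0240 to 0.675.

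**Figure D4:**
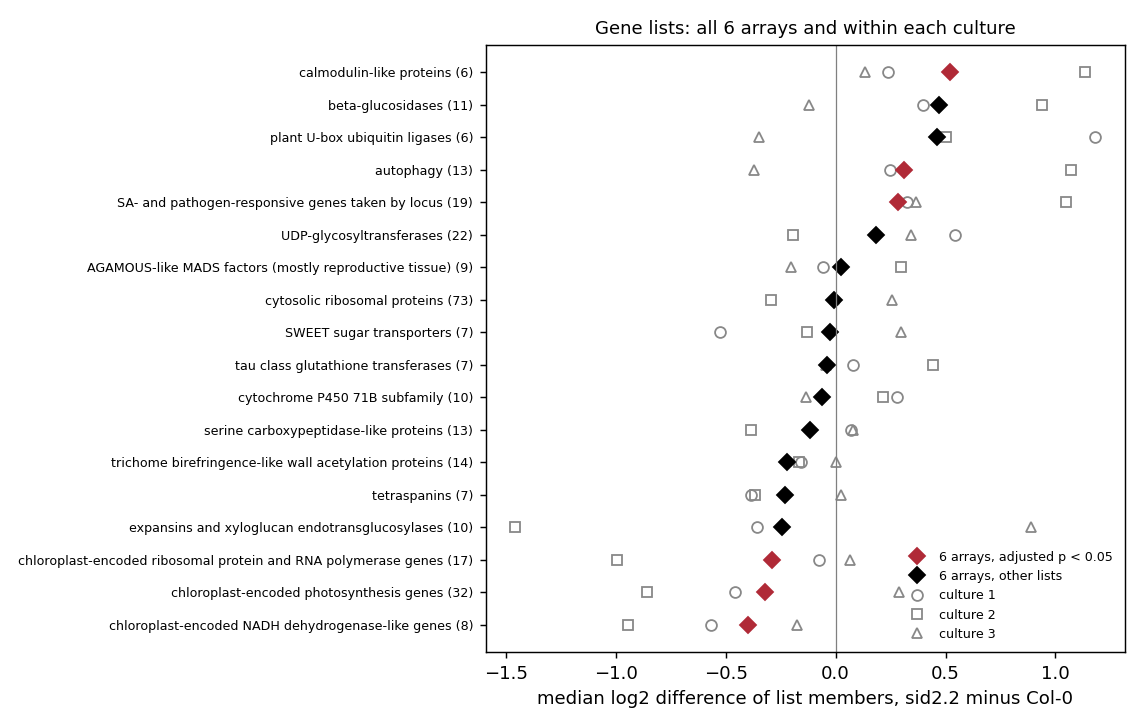
Median log2 difference, sid2.2 minus Col-0, of the members of 18 gene lists (number tested in brackets), over 6 arrays as diamonds, red where the adjusted p was under 0.05, and within each culture as open symbols. For autophagy and chloroplast photosynthesis genes culture 2 (1.07 and -0.86) and culture 3 (-0.37 and 0.29) lie on opposite sides of 0.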

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

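The added alternative without Col-0 replicate 3 and sid2.2 replicate 2 was chosen after seeing the data. With 3 arrays per genotype, and 2 in a genotype once 1 of its arrays is left out, limma's pooled spread carries much of each test. Signal near background limits dim genes such as TRZ1, and no cause was tested for the changes below unless named.

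The 3 calls became 0 with the replicate block, without a low-signal filter and with the stricter one (60%, which leaves out 262177_at), 1 with quantile normalization, 1 without a trend and 5 with the pseudocount. The higher calls were 0, 0, 0, 0, 0 and 4 in these settings and 1 with median centring; the lower calls were 0 with the block and with either filter change. Robust eBayes and culture as a random block kept the count at 3. Leaving out arrays or cultures gave 0 to 728 calls, 0 to 459 higher and 0 to 269 lower. TRZ1, at -3.96, lost its call with the block and without the filter, and left-out arrays gave -4.23 to -3.77; its sid2.2 signals lie below background, so only the bound of 4.65-fold has a fixed size. Culture called 0 probe sets in all 6 alternatives run for it. The number of lists past the set test was 0 with an estimated correlation, 0 with that and the replicate block, and 0 with fry; left-out arrays gave 2 to 9.

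The set test preset a correlation of 0.01 between genes. The estimates were 0.79 for autophagy, 0.32 for calmodulin-like proteins and 0.33 for SA- and pathogen-responsive genes. They were 0.45 for photosynthesis genes, 0.18 for NADH dehydrogenase-like genes and 0.49 for chloroplast ribosomal and polymerase genes. With an estimated correlation the adjusted p was 0.640 for autophagy and 0.595 for the other 5 lists that passed, and 0.675 for all 6 with the replicate block too. With fry, which does not compare a list with other genes, it was 0.597 for autophagy, 0.437 for calmodulin-like proteins, NADH dehydrogenase-like genes and SA- and pathogen-responsive genes, 0.450 for photosynthesis genes and 0.499 for chloroplast ribosomal and polymerase genes. The stricter filter gave 0.0762 for the NADH dehydrogenase-like genes. Over left-out arrays and cultures the adjusted p was 0.000282 to 0.591 for autophagy, 0.00376 to 0.566 for calmodulin-like proteins, 0.000292 to 0.175 for NADH dehydrogenase-like genes, 3.56e-09 to 0.221 for photosynthesis genes, 0.000282 to 0.953 for chloroplast ribosomal and polymerase genes and 3.50e-09 to 0.0548 for SA- and pathogen-responsive genes. It was 0.563 to 0.914 for AGAMOUS-like factors, 0.00852 to 0.727 for cytosolic ribosomal proteins, 0.000282 to 0.690 for expansins, 0.211 to 0.797 for serine carboxypeptidases and 0.270 to 0.985 for SWEET transporters, each with a turn of direction in at least 1 of them. Some lists that did not pass did so with arrays or cultures left out. These were U-box ligases without sid2.2 replicate 3 (0.0240) or culture 3 (0.0366), and UDP-glycosyltransferases without Col-0 replicate 2 (0.0203), sid2.2 replicate 2 (0.0218) or culture 2 (0.00930). Expansins passed without Col-0 replicate 3 (0.00261), sid2.2 replicate 3 (0.00396), culture 3 (0.000282) or Col-0 replicate 3 and sid2.2 replicate 2 (0.0113). Cytosolic ribosomal proteins passed as higher without Col-0 replicate 1 (0.0403), sid2.2 replicate 2 (0.00852) or culture 2 (0.00930), and as lower without culture 3 (0.0341). These passes used the preset correlation. The correlation estimated for this list was 0.54, and with it the adjusted p over all arrays was 0.957. Direction also turned for AGAMOUS-like factors with the stricter filter (0.819), for cytosolic ribosomal proteins with median centring (0.813) and without a filter (0.913), and for SWEET transporters (0.765) and tetraspanins (0.929) without a filter.

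Of 86 named probe sets, 56 kept their direction in all alternatives run for them, and 69 of 1436 values turned, 66 of them with arrays left out, 16 without culture 2 and 8 without culture 3. No probe set that passed turned. Against the threshold, 42 values lost a call and 82 gained one. The gains came with Col-0 replicate 3 left out, alone or with another array, except for PDF1.4 with the pseudocount (limma adjusted p = 0.0470). ATERDJ3B was -0.047 with median centring, and SAG101 -0.023 with quantile normalization and -0.038 with median centring. The lowest and highest log2 differences over left-out arrays were -0.48 and 0.089 for APS3, -0.91 and 0.59 for APS4, -0.50 and 0.088 for AT1G04770, -0.72 and 0.69 for AT2G31790, -0.091 and 1.499 for AT4G14090, -0.52 and 0.22 for AT5G52810, and -0.18 and 0.20 for ATERDJ3B. They were -0.028 and 0.90 for ATG8D, -0.091 and 1.62 for ATG8E, -0.0038 and 0.78 for ATG8F, -0.11 and 1.43 for ATG8H, -1.97 and 1.46 for BCAT4, -0.077 and 2.14 for BGLU28, and -0.077 and 0.56 for CML23. For COR15A they were -3.05 and 0.57, for COR15B -2.74 and 0.030, for COR47 -0.014 and 0.58, for CRT1b -0.11 and 0.73, for DFR -0.044 and 1.23, for GI -0.26 and 2.19, and for GRX480 -0.11 and 1.29. They were -0.16 and 0.38 for LHCB4.1, -0.55 and 0.55 for PRK, -0.47 and 0.19 for PYE, -0.52 and 1.42 for PYK10, -0.13 and 0.63 for QKY, -0.23 and 0.60 for RCA, -0.48 and 0.71 for SAG101, -0.83 and 0.13 for SBPASE, and -0.063 and 0.42 for UGT74B1. The block ended the 3 calls and those of TRZ1 and PDF1.4 in the fit that kept TRZ1, and added 2 lists.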

Other observations

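The tests of wrong genotype labels, of a shared response, of a loss of DNA, of a sequence difference, the mitochondrial values by array and culture, and the chloroplast value without 2 arrays, were chosen after the results they bear on had been seen.

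Some genes, chosen after their values were seen, varied more between arrays of a genotype than between genotypes. BGLU28, the sulfate deficiency marker, had its highest signals in Col-0 replicate 3 (13807) and sid2.2 replicate 2 (14191), with 1256 to 8079 on the other 4 arrays. ATG8E was also highest there, at 1314 and 1629 against 302 to 743. COR15A was lowest there, at 1420 and 949 against 3527 to 15597, while COR47 and LTI30 of the same list were not lowest on both. BCAT4, of methionine-derived glucosinolate synthesis, was lowest there, at 83.4 and 55.1 against 279 to 1498. The wall-loosening expansin list was also lowest on these arrays, with array medians of -0.52 and -0.83 against -0.049 to 0.60.

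Among all 22746 probe sets that are not controls, 3 had a measured signal at least 8 times lower on each sid2.2 array than on each Col-0 array, and 7 one at least 8 times higher. Many of these signals lie below background, so the folds against it are smaller. The 3 lower ones, chosen after their values were seen, were TRZ1 and 2 without a gene name, among them 260431_at with 184, 196 and 124 against 8.60, 11.5 and 2.87. Against background TRZ1 was at least 4.65-fold, 260431_at at least 4.67-fold and the other one at least 1.19-fold lower. The named higher ones were AT5G64190, AT5G51610, AT3G55790, AT4G07340 and AT1G14930. AT3G55790 went from 3.81, 0.930 and 16.2 to 141, 345 and 222, and AT5G64190 from 3.42, 2.202 and 5.13 to 51.8, 140 and 79.1. Of the 2 higher ones without a gene name, 245567_at had 34.98, 2.80 and 66.9 against 639, 1138 and 683, at least 19.5-fold against background. All of the Col-0 signals of the 5 named genes lay below the 95th percentile of the bacterial controls (28.7 to 31.8), so these folds have no fixed size. Against background AT3G55790 was at least 7.26-fold and AT5G64190 at least 2.73-fold higher, while AT5G51610, AT4G07340 and AT1G14930 lay below background on all 6 arrays.

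TRZ1 lost its signal on all 3 sid2.2 arrays while named neighbours on both sides kept theirs. Noise of dim probe sets is argued against: of 2847 other probe sets with a like Col-0 signal, 0.0351% (1) had such an 8-fold drop. A loss of DNA that reaches from ICS1 into TRZ1 stays open. Outside the 15 genes on each side of ICS1, 0 other named probe sets showed such a drop. This count could not decide, because the 2 other probe sets with such a drop have no gene name and so no known position. A sequence difference under the TRZ1 probes may also account for it, and 0 other probe sets of TRZ1 were on the array to tell these apart. A change in TRZ1 transcription in the mutant is the biological alternative, and it was not tested.

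The 3 chloroplast-encoded lists were lower in sid2.2 at the preset correlation, while camera gave each an adjusted p of 0.595 with an estimated one. The actin ratio, a measure of RNA integrity and target length, was higher on the sid2.2 arrays. Poorer priming of RNA without stable poly(A) tails is argued against by medians over the arrays, but the values by culture leave it open. The 6 mitochondrion-encoded probe sets had a median of 0.35 (SE 0.10 over probe sets). With 1 array left out it was 0.048 (without sid2.2 replicate 3) to 0.52. Each was above the bound of 0.5 times the chloroplast shift by more than its SE. The same held within culture 1 (0.082, SE 0.12, bound -0.23), but not within culture 2 (-0.39, SE 0.18, bound -0.43). In culture 3 the chloroplast list rose, so the mitochondrial median of 1.08 (SE 0.19) tests no fall there. These SEs leave out the spread between arrays. Over cultures 1, 2 and 3 the mitochondrial medians moved with the chloroplast ones (-0.46, -0.86 and 0.29), as shared priming would also give. By the bound set beforehand, a drop to under 0.5 times the shift without 1 array, sid2.2 replicate 2 carries the shift. The median of the photosynthesis list was -0.32 over all arrays and -0.14 without sid2.2 replicate 2. It was -0.49 without Col-0 replicate 3 and -0.36 without both. Because of the last value the question was left open, a change of the rule made after the result was seen. A loss of 5' signal would give a negative correlation of the list level with the log2 actin ratio within genotypes. Over 6 arrays Pearson r was 0.25 (exact permutation p = 0.575) and Spearman rho 0.60 (exact permutation p = 0.242). Without sid2.2 replicates 1 and 3, the farthest on the actin ratio, r was 0.80. The arrays then left hardly differed in the centred ratio, so this value says little. The permutations mixed the genotypes, although the ratio varied far less in Col-0 (SD 0.050) than in sid2.2 (SD 1.51). Both p values are therefore rough, and sid2.2 replicates 1 and 3 carry most of the test. The sign of r and rho is the opposite of that predicted, but neither exact p is small. A loss of 5' signal therefore cannot be told apart from a genotype effect.

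Col-0 replicate 3 and sid2.2 replicate 2 deviated together from their genotype means (r = 0.66 across probe sets, which are not independent). Correlations were also positive for Col-0 replicate 1 with sid2.2 replicate 3 (0.43), and for Col-0 replicate 2 with sid2.2 replicates 1 (0.32) and 3 (0.34). Deviations cancel within a genotype, so the first pair by itself pushes these values up, and they do not show further pairs. Cultures shared under other numbers would also give the 0.66, and the within-culture and block values rest on the culture numbers in the labels. The first principal component (55.5% of variance) put Col-0 replicate 3 at 29.8 and sid2.2 replicate 2 at 54.3. The other Col-0 arrays lay at -41.3 and -51.4, and sid2.2 replicates 1 and 3 at 11.9 and -3.37. For a wrong genotype label on Col-0 replicate 3 the tests differ: in the first one, 82 of the 100 probe sets that differed most between the other 4 arrays had it nearer the sid2.2 mean, as such a label would give, while its TRZ1 signal of 149.66, at the Col-0 level, argues against it and replaced the first test after both values were seen. A wrong label on sid2.2 replicate 2 is argued against by 1 of the same 100 lying nearer the Col-0 mean. A candidate explanation is that plants of Col-0 replicate 3 expressed part of the response that separates the genotypes. The deviation of this array correlated with the difference between the other arrays at 0.44, each taken from separate arrays. Col-0 replicates 1 and 2 were subtracted in these differences, so any trait they share would also give a positive value. So would a wrong label on Col-0 replicate 3, and the value cannot decide between these. What would set such a response off, within a culture or at harvest, was not tested.

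The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. In 2 of the 10 splits, the real one included, at least 3 probe sets were called; the highest of the others, 347, came from Col-0 replicates 1 and 2 with sid2.2 replicate 3 against the rest, which points to a structure of the samples other than genotype. At least 6 lists passed the set test in 4 of the 10 splits, with 7 as the highest of the others. Of the other 3 splits that also part all 3 culture pairs, 1 gave the 347 calls and 2 gave 0.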
